A study of Mus musculus with 8 samples.

How the data were processed

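The data were 8 one-colour (Cy3) Agilent whole-genome expression arrays of mouse liver RNA, 1 for each combination of agent (CCl4 or TAA), week of observation (1 or 2) and oligonucleotide (negative control, NC, or miR-29a), with the groups taken from the sample labels. Per the file headers, the authors extracted spot intensity values with Agilent Feature Extraction 10.10.1.1, which subtracted background and detrended each array spatially, and no scaling between arrays was applied to them. The deposited intensity columns used were the processed signal and, for an alternative, the mean spot signal and median local background signal. The deposited flags (0 or 1 per spot; well above background, outlier, saturated) were also those of Feature Extraction, per the file headers. The authors also deposited a matrix of log2 values whose making the labels do not describe. Each column equalled the log2 processed signal of the same array minus 1 constant (within 0.01 for 100% of 55657 probes), with the 75th percentile at about 0 and no centring per gene. Its column medians were −4.04 (CCl4 1-week NC), −4.07 (CCl4 1-week miR-29a), −3.87 (CCl4 2-week NC), −3.81 (CCl4 2-week miR-29a), −3.46 (TAA 1-week NC), −3.47 (TAA 1-week miR-29a), −3.73 (TAA 2-week NC) and −3.57 (TAA 2-week miR-29a). Scale, centring and direction were thus known from the values, and the authors' own account of the scaling was not given in the sources used here.

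Each array held 62976 spots, of which 59305 were non-control spots of 55681 probes; 0 were saturated, and between 126 and 196 spots per array carried an outlier mark. Control spots and outlier-marked spots were left out, which removed 24 probes. Spots of a probe were averaged, and the log2 processed signal minus the array's 75th percentile was used. Probes well above background on at least 4 of the 8 arrays were kept, with the brightest probe per gene by mean over the 8 arrays, giving 18534 features, 12828 of them protein coding and 5028 without a gene symbol. Of the probes, 27656 were named by accession and 3401 by symbol and 321 by older symbol through a RefSeq gene table of another assembly (GRCm38.p6, used for names alone), and 24303 kept the name in the files. Probe coordinates are those of the files, on mm9. A low signal has less precision than a bright one, and 1 array per combination limits the precision of each difference. Where a named gene had other probes with the opposite sign this is stated.

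Differences were fitted with limma 3.58.1 in R 4.3.3, with files read by data.table (version 1.17.8), as an additive model of agent, week and oligonucleotide over all 8 arrays, with 4 residual degrees of freedom, and tested with moderated statistics and Benjamini-Hochberg adjustment at 0.05. Interactions of the oligonucleotide with agent or week added 1 term. Errors of genes are the SE of the fit. Gene lists, 38 in all with 797 genes, 661 of them measured and 77 on more than 1 list, were tested with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation. Lists with fewer than 5 measured genes were not tested, which left 37. Over single matched pairs no test was made, and list medians were set against 10000 random lists of the same size and like mean level. The model, the lists, the alternatives except those named in the closing part, and the rule for named genes were chosen before the data were examined.

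The rule named, in each direction, the 10 genes with the largest mean difference among those past the threshold with the same sign in all 4 pairs. Where fewer than 5 passed, it named the 5 largest among genes of constant sign that were well above background on all 8 arrays, as values. It added the 3 members with the largest absolute difference of each list called by camera and, for miR-29a, a fixed set of collagen, stellate cell and reported target genes. Of these, Eln was under the detection filter. The text gives part of the genes the rule names. The fit was tested on simulated data with known changes over the same 18534 genes in 5 simulations. It recovered 38.8% (TAA against CCl4) and 40.4% (2 weeks against 1 week) of genes changed by 1 log2 unit and 80% and 77.6% of those changed by 2. A shifted list was called in 5 of 5 simulations and an unshifted one in 0 of 5. Simulated noise was alike on all arrays and held no agent by week differences. Genes changed by up to 4 log2 units shared each simulation, which eases the adjusted threshold. The shares of genes recovered may therefore exceed those reachable in the data. The simulated genes varied independently of each other. The simulation thus does not test the preset correlation on lists whose genes vary together, such as Kupffer cell genes (estimated correlation 0.78).

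Alternatives tried were normexp background correction with offset 50 on the mean signal and local background, quantile normalization, each array's median in place of the 75th percentile, the authors' matrix, no filter on dim probes, and a filter on all 8 arrays. Others were the mean over a gene's probes, the matched agent and week combinations as a block, no covariates, trended and robust moderation, the estimated correlation, and leaving out each array and each matched pair. Genes with a miR-29 site in the 3′ UTR were not analysed here, since no transcript sequences were used.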

Results

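Gene expression was measured in 8 liver samples of male mice in which liver fibrosis had been induced for 5 weeks with CCl4 (carbon tetrachloride) or TAA (the usual abbreviation of thioacetamide, another liver toxin; the labels give the abbreviation alone). Over the following 1 or 2 weeks the mice received miR-29a, a microRNA known to repress collagen messenger RNAs, or a negative control nucleotide (NC). Each of the 8 combinations of agent, week and oligonucleotide was represented by 1 sample and 1 one-colour array. There were thus no replicates within a combination. For a gene in the main comparisons, mean ± SE gives the mean of 4 matched differences (n = 4 pairs). The SE is that of the additive fit, equal for agent, week and oligonucleotide, and holds any agent by week difference too. For lists and gene sets ± is the SE between pairs, and for the agent by week term it is that term's SE. The labels do not say whether a sample was 1 animal or a pool. Limma p-values of single genes thus measure only the spread between these samples, and the number of arrays limits the precision. Camera p-values set the genes of a list against the other genes. At the preset correlation of 0.01 they take genes as nearly independent, so they do not stand for the spread between samples. Between 43.9% and 48.4% of the 59305 non-control spots of an array were well above background, and the 75th percentile of the processed signal lay between 136 and 219. The first principal component (50.8% of the variance) ran from the CCl4 1-week arrays (−55.5 for both) to the TAA 1-week arrays (58.8 and 66.4), with the 4 arrays of 2 weeks between −15.2 and 13.1. The TAA 1-week NC array had the lowest mean correlation with the other arrays (0.965 over genes) and stood apart on the second component (52.6, against −32.3 for its miR-29a partner).

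The first comparison asked how miR-29a altered the fibrotic liver. The median of the genes of the circadian clock, which follow the time of day, was above 0 in all 4 pairs. Of 16 measured members 13 were higher with miR-29a, and the list median was 0.68 log2, with medians of 0.36 and 1.04 in the CCl4 pairs and 0.64 and 0.62 in the TAA pairs (1 and 2 weeks in each). Dbp, a transcription factor of the clock's output, was 1.69 ± 0.37 log2 higher (3.23-fold), Per2, a clock repressor, 1.39 ± 0.31 higher and Usp2, a deubiquitinase with a daily rhythm in liver, 2.06 ± 0.36 higher, each in 4 of 4 pairs. Ciart and Per3, further clock repressors, were 2.66 ± 0.62 and 2.25 ± 0.57 higher, though well above background on only 2 and 1 of the 4 NC arrays. Arntl, which encodes the activator BMAL1 and peaks in the opposite phase, was at −1.76 ± 0.49. The list was shifted up in limma's camera test (adjusted p = 6.8e-08), while the adjusted p was 0.148 with an estimated correlation (unadjusted 0.00799). Adjusted over the list alone, 12 of the 16 genes passed 0.05, and over all genes tested 0 passed. The labels do not give the time of day at which livers were taken. The probes lie at mm9 chromosome 7, 52965322 to 52965381 for Dbp, chromosome 1, 93313046 to 93313105 for Per2, and chromosome 9, 43903649 to 43903708 for Usp2.

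**Figure D1:**
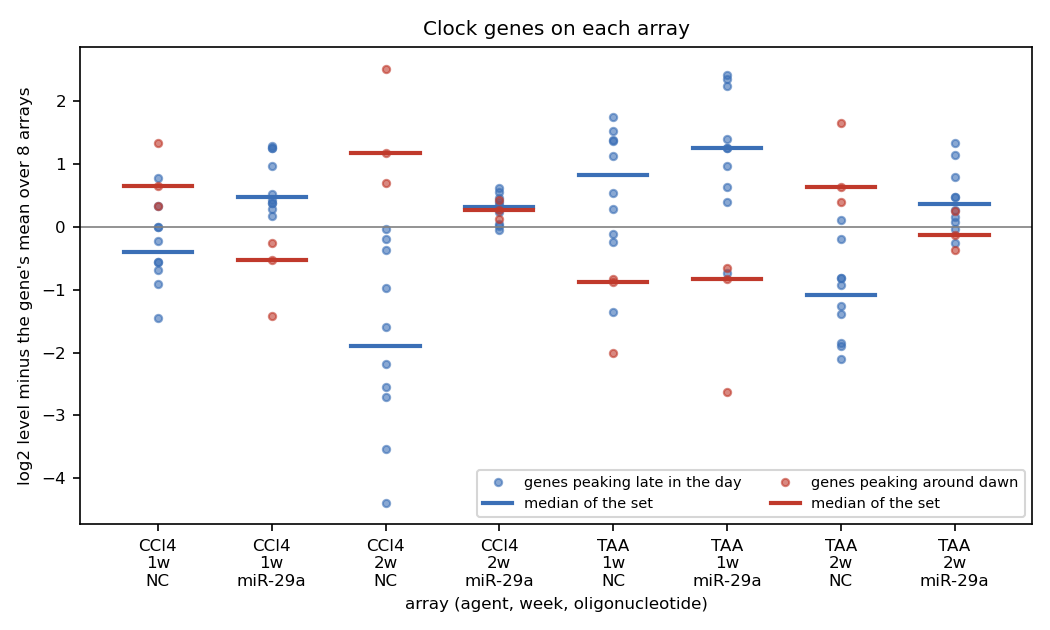
Log2 level of each clock gene on each of the 8 arrays (x axis: agent, week and oligonucleotide), minus that gene's mean over the 8 arrays (y axis). Points are genes, 10 that peak late in the day and 3 that peak around dawn, and lines are the medians of each set; the late-day median is lowest on the CCl4 2-week NC array (−1.89) and highest on the TAA 1-week miR-29a array (1.26).

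Immediate early genes, which respond within minutes to growth factors and stress, were shifted down. Of 18 genes 15 were lower, with a list median of −0.39 and pair medians of −0.26, −0.14, −0.61 and −0.29 (CCl4 1 and 2 weeks, TAA 1 and 2 weeks). The camera adjusted p was 1.7e-06, and the adjusted p was 0.148 with an estimated correlation. Jun, a subunit of the AP-1 transcription factor, had a difference of −0.67 ± 0.23 with 3 of 4 pairs below 0, Nr4a1, an orphan nuclear receptor, −0.92 ± 0.69 and Junb −0.69 ± 0.56. Adjusted over the list alone, 0 of the 18 genes passed in limma, and 3 were at an unadjusted p under 0.05. Under other processing the list median lay between −0.43 and −0.20.

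Inflammatory and proliferation lists were also shifted down with miR-29a, with the largest pair difference of each list in the TAA 1-week pair. Among 19 markers of infiltrating macrophages 18 were lower (median −0.49; pairs −0.30, −0.22, −1.57 and −0.096; camera adjusted p = 3.7e-08). Chil3, a chitinase-like protein of alternatively activated macrophages, was at −1.28 ± 0.50, Lyz2, a macrophage lysozyme, at −1.14 ± 0.55 and Lyz1 at −0.93 ± 0.39, all below 0 in 4 of 4 pairs. Of 23 acute-phase genes 22 were lower (median −0.48; pairs −0.052, −0.071, −1.75 and −0.13; adjusted p = 2.8e-07). Among them Orm3, an orosomucoid, was at −2.11 ± 1.27, Saa1, a serum amyloid, at −1.49 ± 1.01 and Lcn2, a lipocalin released in inflammation, at −2.15 ± 1.71. Cell-cycle genes followed (28 of 32 lower; median −0.24; pairs −0.064, −0.095, −0.75 and −0.31; adjusted p = 5.3e-08), with Kif20a, a mitotic kinesin, at −0.98 ± 0.37, Prc1, a cytokinesis protein, at −0.91 ± 0.30 and cyclin A2 (Ccna2) at −0.79 ± 0.29. With an estimated correlation the adjusted p was 0.645 for each of these 3 lists. Without the TAA 1-week NC array the medians were −0.29 for macrophages and −0.12 for the acute phase, and without its miR-29a partner −0.21, −0.18 and, for the cell cycle, −0.13. Without that whole pair they were −0.15 (macrophage), −0.068 (acute phase, no longer called at adjusted p = 0.0674) and −0.16 (cell cycle). The acute-phase median was −0.76 without the CCl4 1-week miR-29a array, and the cell-cycle median was −0.40 without that array, −0.37 without the TAA 2-week miR-29a array and −0.38 without the CCl4 1-week pair.

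Markers of resident Kupffer cells and neutrophils and the cytokine genes were shifted down as well. All 13 Kupffer cell genes were lower (median −0.63; pairs 0.18, −0.66, −2.17 and 0.092), including Timd4, a receptor for dying cells, at −0.89 ± 0.58 and C1qa, a complement subunit, at −0.78 ± 0.49. Of 9 neutrophil genes 7 were lower (median −1.19; pairs 0.0033, −0.16, −4.84 and 0.0091), with S100a8 and S100a9, the subunits of calprotectin, at −2.23 ± 1.26 and −1.89 ± 1.15. Of 13 inflammatory cytokine genes 10 were lower (median −0.49; pairs −0.13, −0.012, −1.49 and 0.021), with Il1b at −1.43 ± 0.38 and Ccl2, a monocyte attractant, at −1.43 ± 0.52, both below 0 in 4 of 4 pairs. Genes of male-predominant expression in liver were shifted up (19 of 21 higher; median 0.36; pairs 0.11, 0.050, 0.92 and 0.056; camera adjusted p = 8.6e-06). Hsd3b5, a steroid dehydrogenase, was at 2.68 (1.47, 0.79, 7.90 and 0.55 in the pairs), Slco1a1, an organic anion transporter, at 0.99 ± 0.91 and Mup21, a major urinary protein, at 0.75 ± 0.41. Under other processing the cytokine median lay between −0.53 and −0.15. For the 3 lists shifted down the camera adjusted p was 5.1e-07, 0.00319 and 1.0e-05. The adjusted p was 0.645 with an estimated correlation in each of the 4 cases. In limma 0 genes of these 4 lists passed adjusted over the list alone, and 3 cytokine genes were at an unadjusted p under 0.05. Without the TAA 1-week NC array the medians were −0.22 (Kupffer), −0.089 (neutrophil, call ended), −0.15 (cytokine) and 0.11 (male-predominant). Without its miR-29a partner they were −0.26, −0.46 (neutrophil, call ended), −0.26 and 0.18, and without the pair −0.12, −0.056 and −0.11, all 3 calls ended, with 0.084 for the male-predominant list.

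**Figure D2:**
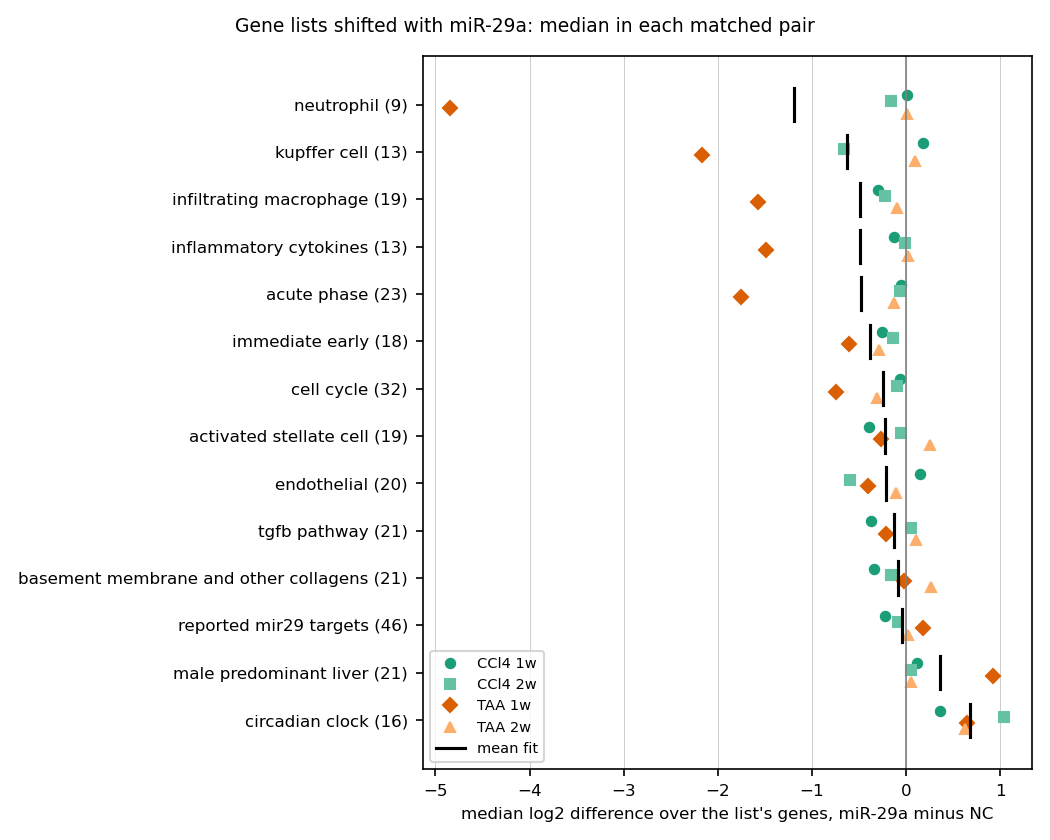
Median log2 difference (miR-29a minus NC, x axis) over the genes of each of the 14 gene lists shifted in the camera test (y axis, measured genes in parentheses). Symbols are the 4 matched pairs and the vertical bar is the median of the genes' mean differences; the TAA 1-week pair lies farthest left in the neutrophil list (−4.84), while all 4 pairs of the clock list lie above 0.

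Fibrillar collagens, the scar matrix, were not shifted (7 genes; camera adjusted p = 0.516, and 0.868 with an estimated correlation), and their median (−0.098) and the direction of the test lay below 0 while their mean (0.045) lay above it. Their pair medians were −0.76 for CCl4 at 1 week, −0.022 for CCl4 at 2 weeks and 0.19 for TAA at both weeks. Col1a1, the main chain of type I collagen (mm9 chromosome 11, 94813115 to 94813174), had a mean of −0.25 ± 0.32, with −1.38 in the CCl4 1-week pair and −0.022, 0.25 and 0.18 in the others. The means of Col1a2 and Col3a1 were −0.12 ± 0.25 and −0.098 ± 0.18. The network collagens of basement membrane, Col4a1 (−0.59 ± 0.27; mm9 chromosome 8, 11199009 to 11199068) and Col4a2 (−0.68 ± 0.29), were below 0 in 4 of 4 pairs. The reported miR-29 targets, 46 measured genes, had a median of −0.045 with 25 lower and 21 higher (pairs −0.22, −0.089, 0.18 and 0.015). Within them Pdgfc, a growth factor for stellate cells (mm9 chromosome 3, 81017572 to 81017631), was at −0.89 ± 0.25 and Dnmt3b, a DNA methyltransferase (mm9 chromosome 2, 153513403 to 153513462), at −0.74 ± 0.21, each below 0 in 4 of 4 pairs. Fbn1, the microfibril protein fibrillin, was at −0.55 ± 0.39, while Dnmt3a, Pdgfrb and Mcl1 had means of 0.11 ± 0.19, 0.045 ± 0.17 and −0.032 ± 0.15, and the integrin chain Itga11 had 1.02 ± 0.50. Another probe of Mcl1 and one of the contractile-cell gene Cnn2 (−0.46 ± 0.23) had the opposite sign.

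Activated stellate cell genes, the myofibroblast signature, had a median of −0.22 (14 of 19 lower; pairs −0.39, −0.051, −0.27 and 0.25). Acta2, which encodes smooth muscle actin, was at 0.45 ± 0.24, with 1.29 in the CCl4 1-week pair. Timp1, an inhibitor of matrix breakdown, was at −0.77 ± 0.55, with −1.95 and −2.30 in the 1-week pairs and 0.68 and 0.49 in the 2-week pairs. Camera called the stellate cell list (adjusted p = 0.0160) and the reported targets (0.0161), and the adjusted p was 0.645 for both with an estimated correlation. In limma 0 genes of either list passed adjusted over the list alone, with 0 and 3 at an unadjusted p under 0.05. The stellate cell call ended without the CCl4 1-week NC (−0.082), CCl4 2-week miR-29a (−0.090) or TAA 1-week miR-29a array (−0.081) and without the CCl4 1-week (−0.17) or TAA 1-week pair (−0.087). The reported targets lost their call without the CCl4 1-week NC (0.032), CCl4 1-week miR-29a (−0.022), CCl4 2-week NC (−0.052) or CCl4 2-week miR-29a array (−0.018) and without the CCl4 1-week (0.036) or CCl4 2-week pair (−0.045). Their median was −0.14 without the TAA 1-week NC, −0.083 without the TAA 1-week miR-29a, −0.092 without the TAA 2-week NC and −0.074 without the TAA 2-week miR-29a array.

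**Figure D3:**
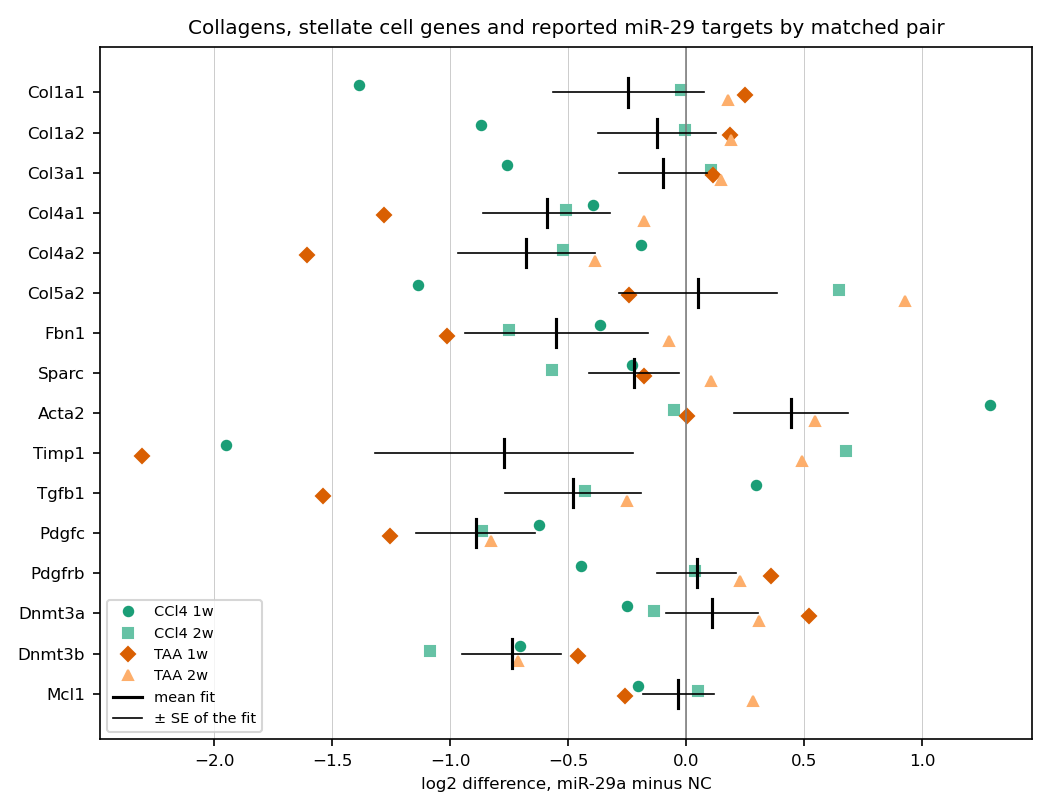
Log2 difference (miR-29a minus NC, x axis) of collagens, stellate cell genes and reported miR-29 targets (y axis). Symbols are the 4 matched pairs, vertical bars the mean of the fit and horizontal lines its ± SE. Pdgfc (−0.89 ± 0.25) and Dnmt3b (−0.74 ± 0.21) lie below 0 in 4 of 4 pairs, and Col1a1 lies at −1.38 in the CCl4 1-week pair alone.

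Among the remaining lists that camera called, endothelial genes had a median of −0.21 (17 of 20 lower; adjusted p = 6.7e-04), TGF-beta pathway genes −0.13 (15 of 21 lower; 0.00443) and basement-membrane and other collagens −0.091 (16 of 21 lower; 0.0135). The adjusted p was 0.645 with an estimated correlation for each. Cdh5, the endothelial cadherin, was at −0.45 ± 0.21. In contrast Vwf, another endothelial gene, lay between −0.0067 and 0.69 with arrays or pairs left out. Ccn2, a connective tissue growth factor, was at −0.58 ± 0.32 and Thbs1, a matrix protein that activates TGF-beta, at −0.51 ± 0.29. Nid1, a basement-membrane linker, was at −0.43 ± 0.26. The endothelial call ended without the CCl4 2-week NC (−0.19), CCl4 2-week miR-29a (−0.082) or TAA 1-week miR-29a array (−0.14), and the median was −0.36 without the CCl4 1-week miR-29a array. The TGF-beta call ended without the CCl4 1-week NC (0.0021) or TAA 1-week miR-29a array (−0.062), and the median was −0.22, −0.055, −0.067 and −0.28 without the CCl4 2-week NC, CCl4 2-week miR-29a, TAA 2-week NC and TAA 2-week miR-29a array. The collagen call ended without the CCl4 1-week NC (0.042), CCl4 1-week miR-29a (−0.099) or CCl4 2-week miR-29a array (−0.020), and the median was −0.16, −0.15 and −0.18 without the CCl4 2-week NC, TAA 1-week NC and TAA 2-week miR-29a array. In limma 0 genes of these 3 lists passed adjusted over the list alone, and 0 were at an unadjusted p under 0.05.

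By single gene, limma called 0 of 18534 genes higher and 0 lower with miR-29a (smallest adjusted p = 1.00). At an unadjusted p under 0.05 there were 524 genes, 307 higher and 217 lower, where 926.7 would be expected by chance. With the matched agent and week combinations as a block there were 1112 in limma, and 0 were called. The sign was the same in all 4 pairs for 2962 genes (16.0%, against 12.5% by chance). On simulated data of this comparison the fit recovered 49.6% of genes changed by 1 log2 unit and 81.6% of those changed by 2. These shares hold for the simulated noise and changes alone. The 0 calls in the data thus do not show that changes of such size were absent. Among the 5 largest differences of constant sign in each direction were 3 genes on no list, Xlr4b (−1.75 ± 0.29), Cd14, a receptor for bacterial lipopolysaccharide (−1.62 ± 0.90), and Pcsk4, a proprotein convertase (1.32 ± 0.28). In all, 14 of 37 lists were shifted, 2 up and 12 down, and 0 with an estimated correlation, with 2 at an unadjusted p under 0.05.

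Each matched pair holds 1 array against 1 array, so its differences have no replicate check. In the CCl4 1-week pair 108 genes were over 2-fold higher and 193 over 2-fold lower with miR-29a. The lowest included Dmkn (−3.89) and the mesothelial surface genes Msln (−2.94) and Upk3b (−2.74). The mesothelial list had a median of −2.09 (percentile 0 among 10000 random lists of like level). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 3.01 higher in the same pair. In the CCl4 2-week pair (133 higher, 92 lower) Dbp was 3.11 higher, and Cyp26b1, which degrades retinoic acid, was at −2.81, whereas in the TAA 2-week pair (173 higher, 156 lower) Cyp26b1 was 6.80 higher, from −2.49 to 4.30. The TAA 1-week pair had 511 genes higher and 731 lower. In it Lcn2 was at 10.05 on the NC array and 1.44 on the miR-29a array (−8.61, mm9 chromosome 2, 32240199 to 32240258). S100a8 differed by −7.40 and Mt2, a metallothionein, by −6.93, while Hsd3b5 was 7.90 and Rgs16, a regulator of G-protein signalling, 5.79 higher. Without the TAA 1-week NC array the mean miR-29a difference of Lcn2 was 0.0053. For TAA minus CCl4 at 1 week, the neutrophil median was 3.28 between the NC arrays and −0.63 between the miR-29a arrays. The acute-phase median was 1.21 and −0.11. For these lists the TAA 1-week NC array thus stood apart more than its partner. Across genes, which are not independent replicates, the 4 pairs' differences correlated between −0.096 and 0.17.

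Whether the miR-29a difference depended on the agent or the week was tested as an interaction. Limma called 0 genes for either (258 and 356 at an unadjusted p under 0.05), whereas camera called 16 lists by agent and 24 by week. None held with an estimated correlation, where the smallest adjusted p was 0.709 by agent and 0.305 by week. Cholesterol synthesis genes had a median of −0.29 with miR-29a at 1 week and 0.57 at 2 weeks (camera adjusted p = 1.3e-16), and fibrillar collagens −0.43 under CCl4 and 0.21 under TAA (9.6e-05). The collagen value under CCl4 was not alike in its pairs, which had medians of −0.76 at 1 week and −0.022 at 2 weeks. In the CCl4 1-week pair the mesothelial list was low as well (−2.09). Without the CCl4 1-week NC array the collagen median over all agents was 0.14.

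The second comparison set TAA against CCl4, the injury agents of the design. Cell-cycle genes were higher with TAA: 27 of 32 were higher, the list median was 0.96 log2 and the pair medians were 1.03, 0.39, 1.30 and 0.74 (1-week NC and miR-29a, then 2-week NC and miR-29a). Plk1, a mitotic kinase (mm9 chromosome 7, 129313220 to 129313279), was 2.39 ± 0.34 higher (5.23-fold), Cenpe, a kinetochore motor, 2.12 ± 0.33 and cyclin B1 (Ccnb1) 2.03 ± 0.47, each in 4 of 4 pairs. Cenpe and Ccnb1 were well above background on 2 of the 4 CCl4 arrays. Infiltrating macrophage genes were higher as well (15 of 19, median 0.78; pairs 1.23, 0.020, 0.57 and 0.85). Among them were Chil3 (2.99 ± 0.50, 7.96-fold; mm9 chromosome 3, 105950485 to 105950544) and the integrin Itgam (1.48 ± 0.43), whereas Gpnmb, a glycoprotein of lipid-laden macrophages, was at −1.48 ± 0.69. The median of all genes was −0.13 in this comparison and, with other scalings, lay between −0.52 and 0.072. Relative to it the list medians were 1.09 (cell cycle) and 0.90 (macrophage), and with normexp 0.57 and 0.59. The list medians themselves were 0.48 and 0.51 with normexp and 0.57 and 0.38 with median scaling. The macrophage call ended with no filter on dim probes. Camera called both (adjusted p = 2.1e-12 and 2.8e-04), and the adjusted p was 0.890 for each with an estimated correlation. Adjusted over the list alone, 18 cell-cycle genes and 1 macrophage gene passed in limma (20 and 9 at an unadjusted p under 0.05), against 0 over all genes tested. Leaving out the TAA 1-week NC array gave a macrophage median of 0.41.

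Kupffer cell, T and NK cell and cytokine genes were shifted up with TAA, by 0.73, 0.44 and 0.64 relative to all genes (own medians 0.60, 0.31 and 0.51). All 13 Kupffer cell genes had a mean difference above 0. Their pair medians were 1.68, −0.50, 0.088 and 0.86 (1-week NC and miR-29a, then 2-week NC and miR-29a). Clec4f, a Kupffer cell lectin, was at 0.81 ± 0.36, Cd5l at 0.77 ± 0.47 and C1qb at 0.74 ± 0.41. Of 14 T and NK cell genes 10 were higher, including Cd3g, a chain of the T-cell receptor complex (1.01 ± 0.15), Lck, its kinase (0.94 ± 0.43), and Thy1 (0.82 ± 0.17). Among cytokines Il1b was at 1.46 ± 0.38 and Ccl4, a chemokine, at 0.74 ± 0.33, while Cxcl1 was at 0.84 ± 0.96 with 1 of 4 pairs above 0. Matrix turnover genes were shifted by 0.34 relative to all genes (median 0.21), with Mmp7, a matrix metalloproteinase, at 2.37 ± 1.00 and Adam12 at 0.75 ± 0.28, and interferon-induced genes by 0.13 (median 0.0050, mean 0.17), with Oas2, an antiviral synthetase, at 1.45 ± 0.45. With median scaling the medians of the T and NK cell, matrix turnover and interferon lists were themselves below 0 (−0.077, −0.18 and −0.39). The camera adjusted p was 0.00381 (Kupffer), 0.00458 (T and NK), 0.0402 (cytokine and matrix turnover) and 0.0436 (interferon), and the adjusted p was 0.890 for each with an estimated correlation. Adjusted over the list alone, 3 T and NK cell genes passed and 0 in the other 4 lists in limma, where 0, 2, 1 and 6 genes were at an unadjusted p under 0.05. With no filter on dim probes each of these calls ended. The agent and week block and the fit without covariates ended the cytokine, matrix turnover and interferon calls. So did the filter on all 8 arrays and the mean over a gene's probes. The Kupffer call ended without the TAA 1-week NC array (0.21), and the median was 1.03 without its miR-29a partner. The cytokine call ended without the CCl4 2-week NC (0.40), TAA 1-week NC (0.21) or TAA 2-week miR-29a array (0.33), with 0.83 without the TAA 1-week miR-29a array. Matrix turnover lost its call without the CCl4 2-week NC (0.12) or TAA 2-week miR-29a array (0.13), with 0.44 without the CCl4 1-week NC and 0.34 without the TAA 1-week miR-29a array. The interferon call ended without the CCl4 1-week miR-29a (0.041), CCl4 2-week NC (0.033), TAA 1-week NC (0.069) or TAA 2-week miR-29a array (0.024). Its median was 0.069, 0.084, 0.11 and 0.056 without the CCl4 1-week NC, CCl4 2-week miR-29a, TAA 1-week miR-29a and TAA 2-week NC array.

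The PPAR-alpha, periportal, pericentral and xenobiotic P450 lists were shifted down with TAA. Camera did not call the hepatocyte, bile acid, cholesterol synthesis or fatty acid synthesis lists, and the direction of the last was up. All 27 genes of PPAR-alpha and fatty acid oxidation were lower (median −0.46, −0.34 relative to all genes; pairs −1.13, −0.56, −0.15 and −0.30). They included Acot1, an acyl-CoA thioesterase (−1.56 ± 0.72), Pdk4, a brake on glucose oxidation (−1.09 ± 0.53), and Cyp4a14, a fatty acid hydroxylase (−0.94 ± 0.83). Periportal genes (18 of 20 lower; −0.43, −0.30 relative) included Etnppl (−1.25 ± 0.64) and Fbp1, a gluconeogenic enzyme (−0.69 ± 0.23). Pericentral genes (18 of 20 lower; −0.38, −0.25 relative) included Slc1a4, an amino acid transporter (−1.37 ± 0.34), Oat, an ornithine aminotransferase (−1.26 ± 0.46), and Slc1a2, a glutamate transporter (−1.25 ± 0.29). Xenobiotic cytochromes P450 (27 of 31 lower; −0.47, −0.34 relative) included Cyp2c38 (−1.09 ± 0.41). The camera adjusted p was 0.00458, 0.0402, 0.0402 and 0.0421 in this order, with an adjusted p of 0.890 for each with an estimated correlation. In limma 0, 0, 3 and 1 genes passed adjusted over the list alone (7, 5, 6 and 7 lower at an unadjusted p under 0.05). Without both TAA 1-week arrays none of these 4 was called, with medians of −0.17, −0.19, −0.20 and −0.12. Of 5 scalings and background corrections, the one used here included, 4 called the PPAR-alpha list and 3 each of the others. The periportal call ended without the CCl4 1-week NC array (−0.36). The pericentral call ended without each of the 4 miR-29a arrays (−0.27, −0.39, −0.34 and −0.32 for CCl4 1 and 2 weeks, TAA 1 and 2 weeks), and the P450 call ended without the CCl4 1-week NC (−0.30), CCl4 1-week miR-29a (−0.35), CCl4 2-week NC (−0.57) or TAA 1-week NC array (−0.15).

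The largest single-gene differences of constant sign were Ly6d (2.84 ± 0.67), Cabyr (2.78 ± 0.78), Cyp21a1, a steroid hydroxylase (2.71 ± 0.80), Lcn2 (2.47 ± 1.71, with 8.65 in the 1-week NC pair) and Cish, a feedback inhibitor of cytokine signalling (2.44 ± 0.38). On the lower side they were Elovl3, a fatty acid elongase (−2.06 ± 0.90), Egr1 (−1.99 ± 0.64), the repressor Bcl6 (−1.78 ± 0.42), Trib3, a stress-induced pseudokinase (−1.69 ± 0.44), and Fam89a (−1.57 ± 0.27). Limma called 0 genes higher and 0 lower (smallest adjusted p = 0.0629), with 5322 at an unadjusted p under 0.05, 1671 higher and 3651 lower. With each array's median in place of its 75th percentile the calls were 235 higher and 5254 lower, and with the agent and week combinations as a block 1593 and 3419. The sign was the same in all 4 pairs for 7053 genes (38.1%, against 12.5% by chance). Camera shifted 11 of 37 lists, 7 up and 4 down, and 0 with an estimated correlation, with 1 at an unadjusted p under 0.05. The CCl4 arrays lay in 1 column of the slide and the TAA arrays in the other, so agent and slide column cannot be told apart here. The 1-week arrays lay in rows 1 and 2 and the 2-week arrays in rows 3 and 4. NC arrays lay in rows 1 and 3 and miR-29a arrays in rows 2 and 4. Week and oligonucleotide thus cannot be told apart from slide row either.

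**Figure D4:**
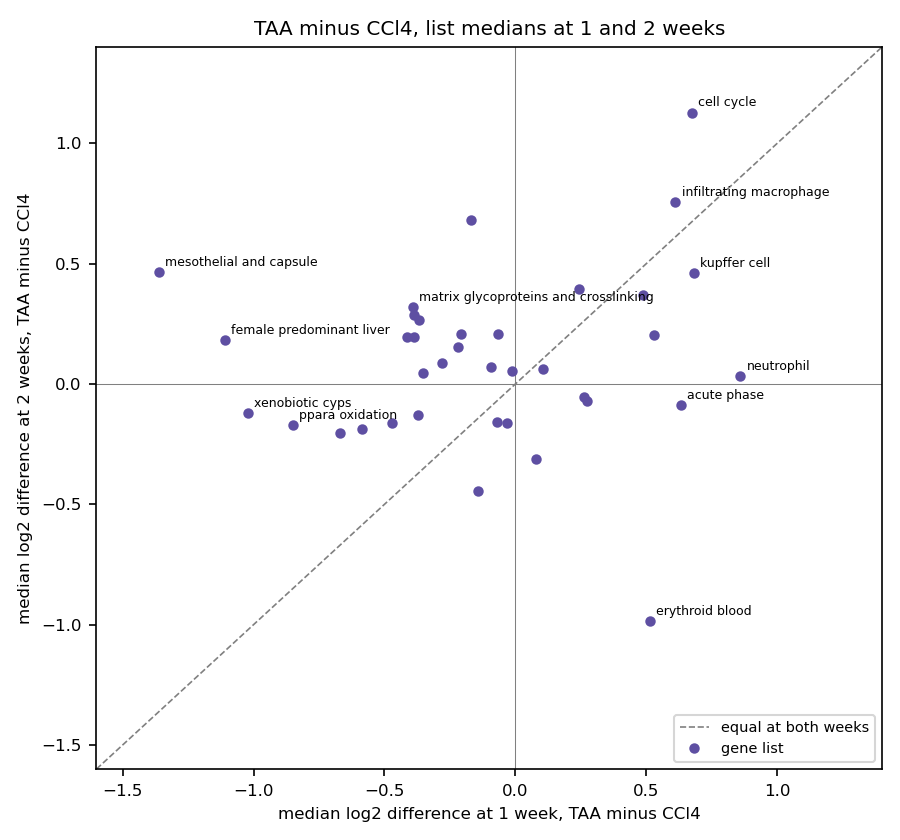
Median log2 difference (TAA minus CCl4) of each gene list at 1 week (x axis) and at 2 weeks (y axis), each the mean of the NC and miR-29a pairs. Points are lists and the dashed line marks equal differences; cell-cycle (0.67 and 1.13) and infiltrating macrophage genes (0.61 and 0.75) lie above 0 at both weeks, and xenobiotic P450 genes lie at −1.02 at 1 week and −0.12 at 2 weeks.

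The third comparison set 2 weeks of observation against 1 week. The fibrillar collagen, matrix glycoprotein and several inflammatory lists were shifted down at 2 weeks, while matrix turnover was not called (camera adjusted p = 0.234). Of 7 fibrillar collagens 5 were lower, with a median of −0.62 and a mean of −0.21. The pair medians were −1.45, −0.32, −0.30 and −0.30 for CCl4 NC, CCl4 miR-29a, TAA NC and TAA miR-29a. The mesothelial list, not called here, also had its lowest median in the CCl4 NC pair (−3.04). Col3a1 was at −0.96 ± 0.18 (1.95-fold lower; mm9 chromosome 1, 45405589 to 45405648) and Col1a1 at −0.93 ± 0.32, both below 0 in 4 of 4 pairs, while Col27a1 was at 1.12 ± 0.66. Of 28 matrix glycoproteins and cross-linking enzymes 20 were lower (median −0.21), including Fbln1, an elastic-fibre protein (−1.21 ± 0.42), Thbs1 (−0.97 ± 0.29) and Mfap4 (−0.66 ± 0.32). Acta2, chosen after its values were seen, was at −1.42 ± 0.24. The activated stellate cell list was not called (10 of 19 genes lower, median −0.13, camera adjusted p = 0.0645). Camera called the fibrillar collagens (adjusted p = 0.0324) and the glycoproteins (1.2e-04), with an adjusted p of 0.683 for both with an estimated correlation. In limma 1 and 0 genes passed adjusted over the list alone (3 and 5 lower at an unadjusted p under 0.05). With no filter on dim probes both calls ended. The agent and week block ended the collagen call too, as did leaving out both TAA 1-week arrays (median −0.59). The collagen call ended without the CCl4 2-week NC (−0.47), CCl4 2-week miR-29a (−0.61), TAA 1-week miR-29a (−0.68) or TAA 2-week NC array (−0.39), and the median was −0.33 without the CCl4 1-week NC array. The glycoprotein call ended without the CCl4 1-week NC array (−0.033), with medians of −0.12, −0.099 and −0.42 without the CCl4 2-week NC, CCl4 2-week miR-29a or TAA 2-week miR-29a array.

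Acute-phase genes were lower at 2 weeks in 21 of 23 cases (median −0.57; pairs −0.42, −0.26, −1.52 and −0.14), with Saa1 at −1.92 ± 1.01 and Orm3 at −2.07 ± 1.27. All 13 Kupffer cell genes (median −0.61; Vsig4, a complement receptor, at −0.85 ± 0.36) and 16 of 19 infiltrating macrophage genes (median −0.44; Chil3 at −1.72 ± 0.50 and the chemokine receptor Ccr2 at −0.81 ± 0.38) were lower too. The camera adjusted p was 3.6e-06, 2.0e-05 and 5.8e-05, with an adjusted p of 0.683 for each with an estimated correlation, and adjusted over the list alone 0 genes passed in limma (0, 1 and 1 at an unadjusted p under 0.05). Without the TAA 1-week NC array the medians were −0.23, −0.19 and −0.28, without its miR-29a partner −1.01, −1.07 and −0.68, and the macrophage median was −0.29 without the CCl4 2-week NC array. Without the pair of TAA NC arrays the Kupffer call ended (−0.19).

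The clock list was shifted down at 2 weeks (10 of 16 lower; median −0.62; pairs −0.79, −0.24, −0.76 and −0.59), with Usp2 at −2.16 ± 0.36, Ciart at −2.24 ± 0.62 and Arntl at 2.36 ± 0.49. The camera adjusted p was 0.00145, and it was 0.628 with an estimated correlation; 12 genes passed adjusted over the list alone. Without both TAA 1-week arrays the median was −0.59 (adjusted p = 0.219, call ended). NRF2 and glutathione genes were higher at 2 weeks (21 of 26; median 0.24), among them Gclc, the limiting enzyme of glutathione synthesis (0.84 ± 0.33), and Mgst3 (0.63 ± 0.30). Pericentral genes were shifted up (17 of 20 higher; median 0.32), with Oat at 1.42 ± 0.46 and Slc1a2 at 0.89 ± 0.29, whereas Por, the electron donor of cytochromes P450, was at −0.81 ± 0.14. The adjusted p was 0.00145 and 0.00341 in camera and 0.628 and 0.683 with an estimated correlation, and 0 and 1 genes passed adjusted over the list alone (limma; 1 and 5 at an unadjusted p under 0.05). The NRF2 median was 0.099 without the TAA 1-week NC and 0.14 without the TAA 2-week NC array. The pericentral call ended without the TAA 1-week miR-29a (0.18) or TAA 2-week NC array (0.19). Without both TAA 1-week arrays the NRF2 and pericentral calls ended, with medians of 0.073 and 0.061.

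Camera called 11 further lists between the weeks, each ended by leaving out single arrays. Xenobiotic P450 genes had a median of 0.33 (adjusted p = 0.00899), with Cyp2c38 at 1.07 ± 0.41. The call ended without the TAA 1-week NC (−0.0084) or TAA 2-week NC array (0.11), with 0.50, 0.55 and 0.63 without the CCl4 1-week NC, CCl4 1-week miR-29a and CCl4 2-week miR-29a array. PPAR-alpha genes had 0.20 (0.0370; ended at −0.0041 and 0.0027 without the TAA 1-week NC or TAA 2-week NC array). Male-predominant genes had 0.29 (0.0207), with calls ended without the TAA 1-week NC (−0.029), TAA 2-week NC (0.044), CCl4 1-week miR-29a (0.27) or CCl4 2-week NC array (0.29). Cytokines had −0.25 (0.0356), with Il1b at −1.12 ± 0.38. The cytokine call ended without the TAA 1-week NC (0.12), TAA 2-week NC (−0.13), CCl4 1-week miR-29a (−0.23) or CCl4 2-week NC array (−0.035), with −0.41 without the CCl4 2-week miR-29a and −0.42 without the TAA 2-week miR-29a array. Interferon-induced genes had −0.23 (0.00349; ended at −0.13 without the TAA 1-week NC array, with −0.16 without its miR-29a partner and −0.14 without the TAA 2-week NC array). Neutrophil genes had −1.11 (0.00899; ended at −0.14 and −0.64 without the TAA 1-week NC or TAA 2-week NC array, with −1.85 without the CCl4 2-week miR-29a and −2.05 without the TAA 1-week miR-29a array). The adjusted p was 0.683 with an estimated correlation for these 6 lists except PPAR-alpha (0.696).

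Immediate early genes had a median of −0.17 (adjusted p = 0.0158), with Ccn2 at −1.18 ± 0.32 and Myc, a growth regulator, at −0.73 ± 0.17, whereas Egr1 was at 1.20 ± 0.64. Their call ended without the CCl4 1-week miR-29a array (−0.089), with −0.27 without the CCl4 1-week NC and −0.25 without the TAA 1-week miR-29a array. B and plasma cell genes had 0.26 (0.0215), with H2-Ob at 0.85 ± 0.17. The B cell call ended without the CCl4 1-week NC (0.23), CCl4 2-week NC (0.13), TAA 1-week miR-29a (0.39) or TAA 2-week miR-29a array (0.28), with 0.40 without the CCl4 2-week miR-29a array. Hepatocyte genes had −0.083 (0.0171; ended at −0.046 and −0.055 without the TAA 1-week or TAA 2-week miR-29a array, with −0.13 without either TAA NC array). Basement-membrane collagens had −0.098 (0.0344), with Col4a5 at −0.68 ± 0.26. This call ended without the CCl4 1-week NC (−0.029), CCl4 1-week miR-29a (−0.11), CCl4 2-week NC (−0.090), CCl4 2-week miR-29a (−0.032) or TAA 2-week NC array (−0.11), with −0.24 without the TAA 1-week NC and −0.22 without the TAA 2-week miR-29a array. Cholangiocyte genes had −0.15 (0.0465), with the chloride channel gene Cftr at −0.54 ± 0.13. That call ended without the CCl4 1-week NC (0.11), CCl4 2-week NC (−0.069), CCl4 2-week miR-29a (−0.061) or TAA 2-week NC array (−0.098), with −0.42 without the TAA 2-week miR-29a array. The adjusted p was 0.628 for the immediate early and B cell lists and 0.683 for the other lists here with an estimated correlation. In limma 1 gene passed adjusted over the list alone among B and plasma cell genes, 1 among xenobiotic P450 genes and 0 in the other 9 lists, with between 0 and 4 of a list's genes at an unadjusted p under 0.05.

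By single gene, limma called 0 higher and 0 lower at 2 weeks (smallest adjusted p = 0.777), with 961 at an unadjusted p under 0.05, 503 higher and 458 lower, where 926.7 would be expected by chance. The sign was constant over the 4 pairs for 2245 genes (12.1%, against 12.5% by chance). The largest differences of constant sign were again taken among named genes well above background on all 8 arrays. On the higher side they were Elovl3 (3.10 ± 0.90), the tubulin gene Tubb2a (2.02 ± 0.27, mm9 chromosome 13, 34166116 to 34166145) and Fitm1, a lipid-droplet protein (1.76 ± 0.35). Next came Slc13a2, a dicarboxylate transporter (1.75 ± 0.23), and Pdk4 (1.73 ± 0.53). On the lower side they were Lcn2 (−2.60 ± 1.71), Cish (−2.53 ± 0.38; mm9 chromosome 9, 107204196 to 107204255), Usp2, Onecut1, a hepatocyte transcription factor (−1.98 ± 0.60), and Saa1. In all, 19 of 37 lists were shifted, 6 up and 13 down, and 0 with an estimated correlation, with 2 at an unadjusted p under 0.05. Without both TAA 1-week arrays limma called 428 genes higher and 77 lower, and camera 8 lists.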

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

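The tests of the TAA 1-week pair alone, of non-hepatocyte cells, of the slide column and of the TAA 1-week NC array alone were chosen after the results were seen, as were the scaling over detected probes and the fit without both TAA 1-week arrays. Lists are given here because their miR-29a difference depended on the agent or the week in camera's test of the interaction, which ended for all of them with an estimated correlation (adjusted p at least 0.709 by agent and 0.305 by week).

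Between agents, the miR-29a difference (TAA minus CCl4, median log2) was −1.17 for acute-phase (adjusted p = 1.1e-08), −1.81 for neutrophil, −0.98 for Kupffer cell, −0.62 for infiltrating macrophage, −0.45 for cytokine and −0.20 for T and NK cell genes. It was −0.40 for the cell cycle, −0.41 for cholesterol synthesis, −0.33 for pericentral and −0.83 for erythroid genes. It was 0.62 for fibrillar collagens, 0.39 for basement-membrane and other collagens and 0.31 for matrix glycoproteins. For the reported miR-29 targets it was 0.29 (−0.19 under CCl4 and 0.11 under TAA, camera adjusted p = 0.00331), for male-predominant genes 0.30 and for xenobiotic P450 genes 0.38. The acute-phase, neutrophil, Kupffer cell, macrophage, cytokine and T and NK cell lists each had their lowest pair median in the TAA 1-week pair. It was −1.75 for acute-phase and −4.84 for neutrophil genes, whose other pair medians lay between −0.16 and 0.0091. Without the TAA 1-week NC array camera called 5 lists by agent, against 16. Fibrillar collagens under CCl4 were at −0.76 at 1 week and −0.022 at 2 weeks.

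Between weeks, the miR-29a difference (2 weeks minus 1 week) was 0.88 for cholesterol synthesis, 0.35 for clock (0.55 at 1 week and 0.83 at 2 weeks), 1.81 for mesothelial, 2.47 for neutrophil, 0.77 for acute-phase, 0.75 for cytokine, 0.71 for Kupffer cell, 0.69 for infiltrating macrophage, 0.29 for interferon-induced and 0.27 for cell-cycle genes. It was 0.20 for activated stellate cell, 0.24 for basement-membrane, 0.46 for matrix glycoprotein, 0.55 for matrix turnover, 0.37 for TGF-beta, 0.38 for cholangiocyte, 0.31 for endoplasmic reticulum stress and 0.13 for p53 target genes. It was −0.42 for bile acid, −0.83 for erythroid, −0.72 for female-predominant, −0.48 for male-predominant, −0.48 for PPAR-alpha and −0.52 for xenobiotic P450 genes. Here too the TAA 1-week pair held the lowest medians of the acute-phase, neutrophil, Kupffer cell, macrophage and cytokine lists.

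The median of the clock list was higher with miR-29a in all 4 pairs. Scaling is argued against, since the lowest list median over 3 other scalings and 1 other background correction was 0.59. A net lowering of Per1 messenger RNA by miR-29a was not seen, since Per1 was 1.04 ± 0.44 higher (between −0.11 and 2.32 in the pairs). Per1 is itself among the late-day genes below, so this cannot exclude a direct action on Per1 beneath their common rise or on its protein. A difference in the time of day at sampling may account for the pattern: 10 genes that peak late in the day exceeded 3 that peak around dawn by 2.01 ± 0.51, above 0 in 4 of 4 pairs. The same gap was −2.07 between 2 weeks and 1 week. Between TAA and CCl4 it was 1.20 ± 0.41, above 0 in 4 of 4 pairs. A shift of the clock's phase by the treatment would give the same values and stays open, since the labels give no sampling time.

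Macrophage, acute-phase and cell-cycle lists were lower with miR-29a, and the TAA 1-week pair alone could account for the acute-phase list, whose median over the other 3 pairs was −0.068 ± 0.023. For the macrophage (−0.15 ± 0.059) and cell-cycle lists (−0.16 ± 0.077) the same test left this open. Over 3 other scalings the medians were −0.50 to −0.54 (macrophage), −0.50 to −0.52 (acute phase) and −0.26 to −0.29 (cell cycle). These values argue against scaling between arrays as the source. The planned test, which also held a background correction, did not decide, with the median nearest to 0 at −0.16 (normexp on the cell cycle). Fewer non-hepatocyte cells of all types stay open, since the macrophage median differed from that of 4 other cell types by −0.41 ± 0.33. A response to miR-29a, which the design names, stays open beside them.

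TAA and CCl4 differed more at 1 week than at 2 weeks. Signal compression linear in a gene's level is argued against as the main source, since a regression on level took 6.99% of the variance of the 1-week difference. The regression does not cover other effects of weak signal. The TAA 1-week arrays had the lowest 75th percentiles of the processed signal, 173 (NC) and 136 (miR-29a), and a part played by this was not tested. A slide column effect as the whole cause is argued against too, since it would act on both weeks alike while limma called 1819 genes for the agent by week term. The TAA 1-week NC array alone is argued against by the miR-29a pair, whose 1-week spread was 2.08 times that of the 2-week pairs. The place of both TAA 1-week arrays on the slide cannot be told apart from their condition, and a faster course of one injury, which may give the same pattern, was not tested.

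Over 33 splits of the 8 arrays into 4 and 4, the real one included, calls as many as the real ones were counted. The count of genes could not decide, since the real split called 0 in each comparison and all 33 splits must reach that. By the count of lists, chance could not be excluded in any of the 3 comparisons. With miR-29a another split called 2369 genes in limma. The real split shifted 14 lists, 20 splits gave as many and the highest other gave 27. Between agents the real and the highest other split called 0 genes. Genes at an unadjusted p under 0.05 in limma numbered 5322 in the real split and 5723 in the highest other. Lists shifted numbered 11, with 23 splits giving as many and 24 as the highest. Between weeks limma called 0 genes and another split 875, and 19 lists were shifted, with 7 splits giving as many and 23 as the highest. The splits with 2369 and 875 genes set CCl4 at 1 week and TAA at 2 weeks against the rest. They point to a structure of the samples by agent and week together. Other splits thus hold differences between conditions and do not measure chance alone.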

How the results depend on the processing

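The scaling over detected probes and the fit without both TAA 1-week arrays were chosen after the data were seen; where a result changed, the cause was not tested, except that fits on fewer arrays have fewer samples. With TAA, genes called higher and lower were 6 and 0 with normexp, with a filter on all 8 arrays and with detected probes, 7 and 4 with quantile normalization, 235 and 5254 with median scaling, 1593 and 3419 with the agent and week block, 15 and 3 with no covariates, and 5 and 0 with trended robust moderation. Lists shifted with TAA numbered 7 with quantile normalization, 5 with the filter on all 8 arrays, 5 with the mean of a gene's probes, 6 with the block, 5 with no covariates, 18 without both TAA 1-week arrays and 0 with the estimated correlation. Between weeks 11 lists were shifted with no filter, 8 without both TAA 1-week arrays (428 genes higher, 77 lower) and 0 with the estimated correlation, which also gave 0 with miR-29a and ended the calls of activated stellate cell genes (−0.22) and reported targets (−0.045), both at adjusted p = 0.645. Reversed were, between weeks with quantile normalization, the hepatocyte list (0.016), Ahsg (0.024) and Trf (0.016), and, with no filter, fibrillar collagens with miR-29a (0.026). Without both TAA 1-week arrays the reversed values were, for TAA, Gpnmb 0.19, Cxcl1 −0.27, Hsd17b13 0.13, Cyp4a14 0.15 and the direction of the test of P450 genes (median −0.12), and between weeks PPAR-alpha −0.038, P450 −0.066, Fcmr −0.095, Ehf 0.078, Cxcl1 0.17, Slco1a1 −0.093, Gsta2 −0.29 and Acot1 −0.024. Leaving out arrays or pairs gave 0 genes in each comparison and interaction (limma), 11 to 21 lists with miR-29a, 7 to 15 with TAA, 10 to 24 between weeks, and 5 to 21 and 17 to 25 for the interactions by agent and by week. With miR-29a the ranges were −0.33 to −0.081 for activated stellate cell genes, −0.14 to 0.036 for reported targets, −0.23 to 0.14 for fibrillar collagens, −3.37 to 0.0053 for Lcn2, −0.0067 to 0.69 for Vwf, −0.069 to 1.69 for Slco1a1, −0.47 to 0.14 for Col1a1, −0.30 to 0.16 for Col1a2, −0.18 to 0.12 for Col3a1, −0.24 to 0.45 for Col5a2, −0.069 to 0.21 for Pdgfrb, −0.059 to 0.27 for Dnmt3a and −0.15 to 0.064 for Mcl1. With TAA they were −0.35 to 1.52 for Cxcl1 and −1.69 to 0.052 for Cyp4a14, and between weeks −0.42 to 0.15 for the cholangiocyte list, −0.90 to 0.16 for Ehf, −1.59 to 0.30 for Cxcl1 and −1.56 to 0.14 for Tnfaip3. Of the values of called lists under other settings, 132 of 144 (miR-29a), 87 of 143 (TAA) and 185 of 247 (weeks) kept direction and call. With arrays left out 124 of 144, 104 of 132 and 166 of 228 did. The miR-29a counts leave out the activated stellate cell and reported target lists. With arrays left out these kept 7 and 6 of 12 calls, and under other settings 11 of 12 each. A fit that lacks a combination's array pools the spread of the others. Pairing by replicate number was not possible because each combination has 1 array. For miR-29a the matched pairs entered as the agent and week block, where limma called 0 genes (smallest adjusted p = 0.785). A slide or scan block was not run, since there was 1 slide and 1 scan. Genes near background are limited by their signal.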

Other observations

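The agent by week term was fitted after the data were seen. Limma called 1819 genes for it (1023 with the TAA minus CCl4 difference higher at 2 weeks and 796 lower; smallest adjusted p = 0.0266; 5630 at an unadjusted p under 0.05). TAA and CCl4 differed over 2-fold for 3673 genes at 1 week and 417 at 2 weeks. Apom, a lipoprotein carrier of sphingosine phosphate, was at −2.95 log2 with TAA at 1 week and 0.65 at 2 weeks (difference 3.59 ± 0.35, adjusted p = 0.0266). Pon2, a paraoxonase, was at −2.19 and 0.55 (2.74 ± 0.23) and Ogn, a matrix proteoglycan, at −1.87 and 0.93 (2.80 ± 0.43, adjusted p = 0.0299). In the other direction Asns, which makes asparagine, was at 2.24 and −2.65 (−4.90 ± 0.79, adjusted p = 0.0316). Derl3, a protein of endoplasmic reticulum degradation, was at 2.69 and −1.86 (−4.55 ± 0.95, adjusted p = 0.0459), and Cyp21a1 at 4.64 and 0.79 (−3.85 ± 0.51, adjusted p = 0.0267).

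Of the lists, camera called xenobiotic P450 genes (median −1.02 at 1 week and −0.12 at 2 weeks; adjusted p = 0.0187), and the adjusted p was 0.933 with an estimated correlation. Periportal genes had −0.59 and −0.19, with 4 of 20 members called higher at 2 weeks, and matrix glycoproteins −0.39 and 0.32, with 4 of 28 called higher. Erythroid genes went from 0.51 to −0.98 and female-predominant liver genes from −1.11 to 0.18, and neither list was called (adjusted p = 0.0938 and 0.241). The over-2-fold counts of the single pairs were 4257 (NC) and 4065 (miR-29a) at 1 week and 604 and 738 at 2 weeks. Across genes, which are not independent replicates, the differences of the pairs correlated at 0.69 within 1 week, 0.45 within 2 weeks and between 0.12 and 0.32 across weeks.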
